A study of Mus musculus with 12 samples.

How the data were processed

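Single cells of mouse retina were profiled by Drop-seq, which captures 3' ends of polyadenylated RNA on barcoded beads and counts unique molecular identifiers (UMIs). Pups of the C57B6 strain were sampled at postnatal day 14 (P14) or 17 (P17). In the oxygen-induced retinopathy (OIR) groups, pups breathed 75% oxygen from day 7 to day 12 with a foster mother and room air afterwards, which first stops and later deranges vessel growth. Control pups (NORM) stayed in room air. Retinas were used whole or after a depletion of rods. The labels place 12 libraries in 8 groups. NORM has 1 library for each age and fraction. OIR has 2 rod-depleted and 3 whole-retina libraries at P14, and 1 rod-depleted and 2 whole-retina libraries at P17. Run dates in the labels put 1 NORM and 1 OIR library on the same run in 2 cases, both at P14 (rod-depleted NORM with OIR replicate 2, and whole-retina NORM with OIR replicate 1). Both P17 NORM libraries share a run that is stated for no OIR library, the run of the 2 whole-retina OIR libraries at P17 is not given in the labels, and whole-retina OIR replicates 2 and 3 at P14 share another. No statement in the labels says which libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical.

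The authors deposited 1 table of 21408 genes by 31271 cells. Its values are natural logs, as the deposited values themselves show: the exponential minus 1 adds up to 10000 in every cell, and 100% of the non-zero values lie within 0.05 of a whole UMI once the size of 1 UMI in that cell is known. The deposited natural-log unit is therefore ln(1 + UMI count / cell total × 10000). Per the submitters' processing notes, bcl2fastq, STAR 2.4.0 and the mouse build mm10 or GRCm38 were used. The gene annotation, the handling of reads that map to several genes and any doublet removal are not given in the sources used here. The fewest detected genes of a cell were 101 and the most UMIs 9995, so cells outside these limits were not analysed here. Columns were matched to libraries by name, and 5799 columns in 7 sets that match no library were not used. For whole-retina NORM at P14 the columns carry replicate number 8 instead of 1, so this match is less sure than the others; many counts of calls depend on this library. The 25472 cells of the 12 libraries held 36182149 UMIs. Of the gene symbols, 21038 matched the GRCm38 annotation (GENCODE release M21), from which positions were taken.

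From these values, UMI counts per cell were recovered for depth, counting intervals and a check of doublets. Cells with at least 200 detected genes were kept (24772 cells). The 2000 variable genes were those with the highest dispersion for their mean level, and 30 principal components were taken from them. Each cell was joined to 15 exact nearest neighbours, and links were weighted by the share of common neighbours (Jaccard index). Clusters came from Leiden (leidenalg 0.10.2) at resolution 1.0 with seed 1. A cluster took the class with the highest score among 21 marker sets if at least 3 of its markers were detected in 10% of its cells and its 10 leading genes did not go against the name. Classes are written X-like. No doublet caller was used for the main results. Scrublet, run in Scanpy 1.11.5, called 0.431% to 1.91% of the cells of a library, and leaving those out was an alternative.

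For each library and class with at least 20 cells, the mean normalised value per gene was rescaled to 10000 and tested as log2(value + 0.2) with limma 3.58.1 in R 4.3.3, using moderated statistics with a trend. A log2 difference on this scale understates the change of low genes. Genes needed a mean of at least 0.2 per 10000 and a value above 0 in at least 3 libraries. A class was tested with at least 2 NORM libraries, 2 OIR libraries and 2 residual degrees of freedom. The main model held oxygen, age and fraction as additive terms over all ages and fractions, because NORM has 1 library in each. A model with an oxygen effect per age gave the differences at P14, at P17 and their interaction. Adjusted p-values are Benjamini-Hochberg values within a class, with a threshold of 0.05, and all tests are two-sided. Standard errors follow each log2 difference after ±, and library means carry the SD. For genes with 0 UMIs in all NORM libraries of a class, the difference is a lower bound against a floor of 3 UMIs over the group. With 1 to 3 UMIs the ratio of summed UMIs is given with its exact 95% counting interval, which covers counting error only.

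The 30 gene lists were tested with camera at a preset correlation of 0.01, camera with an estimated correlation and fry, where at least 4 members were measured in a class, and their adjusted p-values are over lists within a class. They are hypoxia and HIF targets, glycolysis, nuclear-encoded respiratory chain, mitochondrially encoded genes, reactive gliosis, Müller homeostasis, complement, interferon and antigen presentation, inflammatory cytokines and NF-kB, senescence and its secretory factors, BCL2 family and apoptosis, angiogenesis and tip cell, blood-retina barrier, neutrophil and extracellular trap, rod phototransduction, cone phototransduction, crystallins, immediate early genes, heat shock, unfolded protein and integrated stress response, cell division, cytosolic ribosome, cholesterol and lipid, synapse, extracellular matrix, microglial activation, microglial homeostasis, antioxidant and metal genes, a sex chromosome check and haemoglobin.

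Shares of cells per class were compared with exact permutation tests of the logit share, with 0.5 cells added, in a model with age and fraction. Oxygen labels were permuted within each age and fraction (72 arrangements), so that no p can fall below 0.0139. Fraction labels were permuted within each age and oxygen group (120 arrangements). Scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15 were used.

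Groups, models, markers, gene lists, alternatives and the rule for named genes were chosen before the data were examined, except where a setting is said to have been chosen after seeing the data. The rule names, in the class with the most calls, the 10 highest and 10 lowest log2 differences among genes past the threshold. In the other classes it names the 4 highest and 4 lowest, or the 4 lowest p-values where none pass. It adds the 4 members with the lowest p of each called list, genes fixed for every class (among them Vegfa, Gfap, Cdkn1a, Bcl2l1, Hmox1, Il1b and Edn2), the 4 highest and 4 lowest for age and for interaction in the class with the most calls, and genes such as Sag and Gnat1 as signs of rod RNA. The text prints part of the list members, and some genes that the rule names are not reported here; a gene named outside the rule is said to have been chosen after its values were seen. A planned edgeR test and a planned DESeq2 test of the counts were not run, since these tests were kept for files deposited as counts and this one holds natural logs; voom on recovered UMI sums stands in for them. Alternatives varied the pseudocount, the filters on genes and cells, the weights, the scaling, the clustering resolution and the libraries used. Chosen after seeing the data were voom on recovered UMI sums, cells thinned to 300 UMIs, leaving out the run of whole-retina OIR replicates 2 and 3 at P14, and a test of endothelial-like and astrocyte-like cells with at least 10 cells per library.

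The fit was tested on simulated data for 5 classes, drawn from the real genes, means and library sizes with 2-fold or 4-fold changes put into known genes. It called 31.1% of 2-fold and 96.4% of 4-fold changes among 7223 genes for Müller-like cells, with 6 false calls, and 63.3% and 100% among 6829 genes for rod-bipolar-like cells, with 7 false calls. For pericyte-like cells it called 8.60% and 60.0% among 6669 genes with 19 false calls, for rod-like cells 22.4% and 90.1% among 6822 genes with 18 false calls, and for microglia-like cells 2.38% and 39.2% among 6574 genes with 0 false calls. The median recovered log2 was 0.71 to 0.81 for a true value of 1 and 1.62 to 1.74 for a true value of 2. Genes were drawn independently with 1 common spread per class, so the simulated data held no run effects and no correlation between genes. The false calls above therefore do not measure the error of the real fits, where such structure can add more. In a simulation of the share test on amacrine-like cells, true logit changes of 0, 1 and 2 came back as -0.039, 1.06 and 1.92.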

Results

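The 12 libraries held 932 to 3415 cells each, and 24772 of 25472 cells had at least 200 detected genes. Median UMIs per cell ranged from 304.5 in the whole-retina NORM library at P17, the shallowest, to 1710 and 1794 in the whole-retina OIR libraries at P17. At P17 oxygen is thus tied to depth in whole retina, while the rod-depleted libraries had medians of 1016 (NORM) and 945 (OIR). OIR and NORM share a stated run only at P14, once in rod-depleted and once in whole retina.

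Neurons, glia, vessel cells and immune cells of the retina were all recovered. Clustering gave 28 clusters, of which 26 took a class from their markers. Rod-bipolar-like cells were led by Pcp2 and Sebox in a cluster of 3169 cells, Müller-like cells by Cyr61, Slc1a3 and the stress gene Atf3 in a cluster of 2198 cells and by Rlbp1, Spc25 and Glul in a cluster of 877. Cone-like cells (1405) showed Pde6h and Opn1sw, and the largest rod-like cluster (2009 cells) Guca1b, Nrl and Pex5l. Ganglion-like cells (333) were led by Nefl and Sncg, pericyte-like cells (375) by Mgp and Rgs5, endothelial-like cells (267) by Cldn5, Ly6c1 and Pltp, and horizontal-like cells numbered 236. Microglia-like is short for a class of microglia or macrophages, which were not told apart, so its calls cannot be assigned to microglia alone. The class formed a cluster led by Ctss, C1qb, Ccl3 and Ccl4 (222 cells) and one led by Cd74, Pf4, Lyz2 and Hmox1 (187 cells). Astrocyte-like cells (168) had S100b, Lcn2, Gfap and Chi3l1 among their leading genes, of which Lcn2 and Chi3l1 stand out in a single library over all cells, rod-depleted OIR replicate 2 at P14 (Lcn2 8.98 per 10000, highest other 0.453; Chi3l1 highest other 0.343). Lens-like cells (694), led by crystallins, occurred in 2 libraries alone. The 2 unnamed clusters held 565 cells led by Igfn1 and Cabp2 and 271 cells led by Optc and Crhbp.

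Rod depletion worked. Rod-like cells made up 32.0 ± 13.5% of whole-retina libraries (n = 7) and 0.492% of rod-depleted ones (n = 5). Rod-bipolar-like cells rose from 12.0 ± 3.87% to 39.8 ± 4.83%, Müller-like cells from 8.25 ± 1.58% to 18.8 ± 4.90%, pericyte-like cells from 0.593 ± 0.454% to 3.09 ± 1.67%, microglia-like cells from 0.782 ± 0.463% to 3.15 ± 1.64%, endothelial-like cells from 0.411 ± 0.331% to 2.15 ± 1.03% and astrocyte-like cells from 0.332 ± 0.129% to 1.16 ± 0.372%. Amacrine-like cells fell from 15.4 ± 2.92% to 8.13 ± 2.30%. These 8 classes reached the smallest p that 120 arrangements allow (0.00833, adjusted 0.0135). Horizontal-like cells rose from 0.689 ± 0.283% to 1.26 ± 0.459% (exact permutation p = 0.0333, adjusted 0.0481), which makes 9 of 13 classes. Cone-like (adjusted p = 0.80), ganglion-like (0.442), lens-like (0.266) and cone-bipolar-like cells (0.065) did not pass.

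No class changed its share between OIR and NORM past the threshold (0 of 13). Astrocyte-like cells were 0.745 ± 0.529% of OIR libraries (n = 8) against 0.539 ± 0.436% of NORM libraries (n = 4; exact permutation p = 0.0278), and endothelial-like cells 0.811 ± 0.915% against 1.79 ± 1.33% (p = 0.0556), both with an adjusted p of 0.361. Every other class had an adjusted p of at least 0.767. With 72 arrangements a single class could at best have reached an adjusted p of 0.181, so this test could miss a large change.

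**Figure D1:**
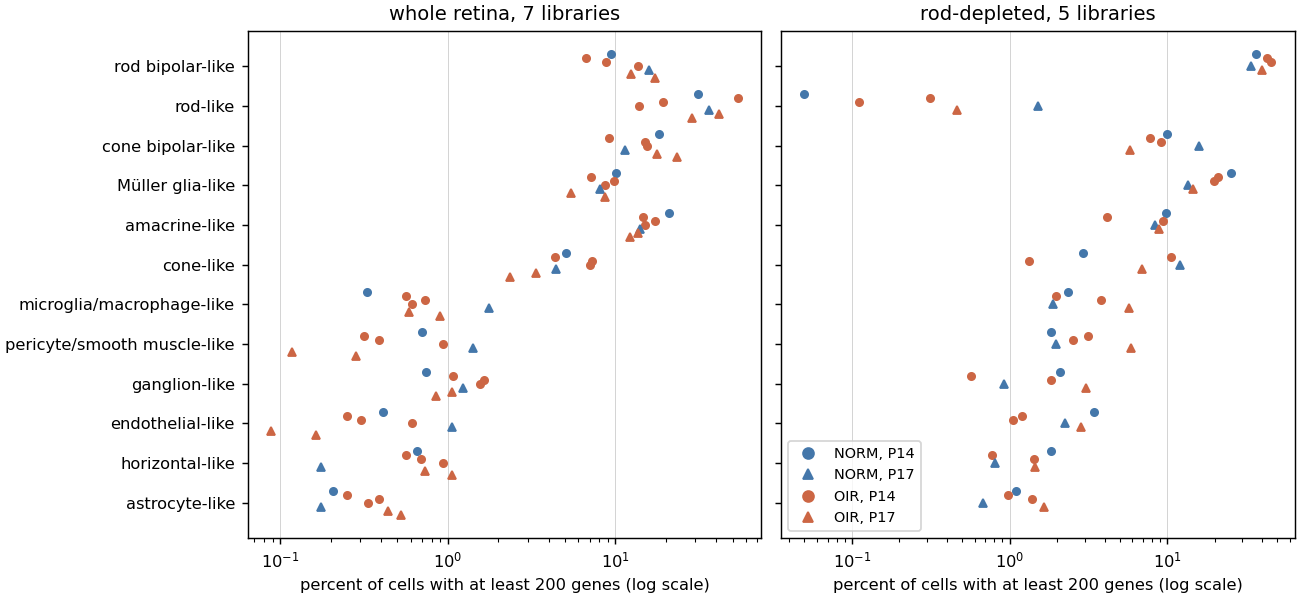
Percent of the cells of each library in each class, on a log axis, with 1 point per library by oxygen group (NORM n = 4, OIR n = 8) and age, whole retina and rod-depleted retina in separate panels. Rod-like cells are near 32.0% in whole retina and 0.492% after depletion.

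In Müller-like cells of OIR retina 15 genes rose and 1 fell. Ndufa4l2, which lowers complex I activity in hypoxia, rose by 3.26 ± 0.27 (adjusted p = 2.9e-06), to 9.95 ± 4.15 per 10000 in OIR (n = 8, against NORM n = 4). The vessel peptides adrenomedullin (Adm, 2.98 ± 0.36, adjusted p = 0.00052) and apelin (Apln, 2.14 ± 0.28, adjusted p = 0.0010) rose as well, and all 8 OIR libraries lay above the highest NORM library for these 3 genes. So did the stress regulator Nupr1 (2.37 ± 0.42, adjusted p = 0.014) and the matrix gene Fn1 (1.84 ± 0.31, adjusted p = 0.011), again in 8 of 8 libraries. Igfbp5 rose by 1.95 ± 0.34 (5 of 8), and Loxl2, a matrix cross-linking enzyme, by 1.47 ± 0.29 (7 of 8). Fam159b alone fell, by 1.35 ± 0.26 (7 of 8 libraries below NORM). In all, 16 of 7396 genes passed, against 867 at an unadjusted p below 0.05. Ndufa4l2, Adm and Apln passed whichever library was left out. The count fell to 7 without the rod-depleted OIR library at P17, which Fn1, Igfbp5 and Nupr1 need, and rose to 27 without the whole-retina NORM library at P14. Igfbp5 and Nupr1 were also lost without the rod-depleted NORM library at P14, and Nupr1 without the whole-retina one. Loxl2 and Fam159b held in 2 of 12 such fits. At P17 the larger cluster, led by Cyr61 and Atf3, held 93.2% of OIR and 21.7% of NORM Müller-like cells in whole retina, and 54.3% and 59.4% in rod-depleted retina.

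Several well-known injury genes of Müller cells lay just short of the threshold. Gfap, the filament protein of reactive glia, went from 0.0802 ± 0.0805 to 1.34 ± 0.916 (2.08 ± 0.44, adjusted p = 0.058), Vegfa from 7.87 ± 3.88 to 18.0 ± 4.65 (1.27 ± 0.26, adjusted p = 0.055) and the protease inhibitor A2m from 0.00688 ± 0.00795 to 0.432 ± 0.259 (adjusted p = 0.054), each with 8 of 8 OIR libraries above NORM. In the whole-retina pair of the same run at P14, however, Vegfa stood at 13.3 in NORM and 13.8 in OIR (log2 difference 0.056, against 0.92 in the rod-depleted pair). Atf3, a leading gene of the larger Müller-like cluster, had 1.95 ± 0.42 (adjusted p = 0.058, 4 of 8). As a list, reactive gliosis was higher (13 members, 0 past over all genes and 9 adjusted over the list alone, adjusted p = 8.4e-08, but 0.156 with an estimated correlation), led by Gfap, A2m, Osmr (1.22 ± 0.30) and Nes (1.41 ± 0.37). Hypoxia and HIF targets were higher (20 members, median 0.48, 2 past over all genes and 7 over the list alone, adjusted p = 1.8e-05, and 0.054 with an estimated correlation). Senescence and its secretory factors (18, median 0.75, 1 and 4, adjusted p = 7.0e-06, 0.16 with an estimated correlation) were led by Igfbp5, Igfbp2 and Gadd45g. Immediate early genes (17, median 0.67, 0 and 7, adjusted p = 8.1e-06, 0.25 with an estimated correlation) held Egr2 (1.37 ± 0.36), Klf4 and Ier2. Interferon and antigen presentation (14, median 0.48, 0 and 5, adjusted p = 0.00092, 0.23 with an estimated correlation) held H2-D1 (1.06 ± 0.24) and Ifi27 (1.19 ± 0.29).

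Müller-like cells also had a higher extracellular matrix list (7 members, median 0.44, 1 past over all genes and 1 over the list alone, adjusted p = 0.0048, 0.23 with an estimated correlation), with Fn1 in front. NF-kB and cytokine genes (7, median 0.75, 0 and 1, adjusted p = 0.042, 0.34 with an estimated correlation) were led by Nfkbiz (1.16 ± 0.33), and angiogenesis genes (8, median 0.38, 1 and 2, adjusted p = 0.032, 0.34 with an estimated correlation) by Apln. Müller homeostasis was lower (17 members, median -0.22, 0 and 2, adjusted p = 0.032, 0.34 with an estimated correlation). In it, glutamine synthetase (Glul) went from 141 ± 34.7 to 90.0 ± 19.9 (-0.61 ± 0.16, adjusted p = 0.14, 5 of 8 below NORM), and Gpr37 had -0.62 ± 0.20, the water channel Aqp4 -0.51 ± 0.23. Rod phototransduction was lower (22, median -0.30, 0 and 0, adjusted p = 0.0049, 0.72 with an estimated correlation), led by Sag (-1.05 ± 0.42), and this list turned around without the whole-retina NORM library at P17. Glycolysis in Müller-like cells had a median of 0.16 over 18 genes and did not pass (adjusted p = 0.26).

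Rod-bipolar-like cells of OIR retina had higher levels of several enzymes of glycolysis and targets of hypoxia, although the glycolysis list did not hold with an estimated correlation (adjusted p = 0.288). Hexokinase 2 (Hk2), the first enzyme of glycolysis, rose by 2.25 ± 0.23 (adjusted p = 5.5e-05), from 0.0505 ± 0.0344 (n = 4) to 1.07 ± 0.375 (n = 8). Phosphofructokinase (Pfkp) rose by 1.73 ± 0.19 (adjusted p = 0.00012), from 4.80 ± 1.08 to 17.2 ± 4.24. Pdk1, which inhibits pyruvate dehydrogenase in mitochondria, rose by 1.59 ± 0.22 (adjusted p = 0.0020). Bnip3, a mitophagy receptor, rose by 1.45 ± 0.22 (2.83 ± 0.302 to 8.47 ± 2.76), Aldoc by 1.23 ± 0.18, Ldha by 1.08 ± 0.20 (5.76 ± 1.32 to 12.3 ± 2.82) and Vegfa by 1.02 ± 0.17 (adjusted p = 0.0048, 1.20 ± 0.279 to 2.53 ± 0.558). The tyrosine kinase Matk rose by 2.59 ± 0.22 (adjusted p = 1.1e-05), Selenbp1 by 1.81 ± 0.20 and Gm15283 by 1.76 ± 0.27. All 8 OIR libraries exceeded NORM for these genes, save Ldha with 7.

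Antigen-presentation genes rose in rod-bipolar-like cells too. H2-K1 rose by 1.23 ± 0.20 (adjusted p = 0.0050) and Stat3 by 1.14 ± 0.22 (adjusted p = 0.018). A2m was 45.3-fold higher (95% counting interval 12.4 to 376) and H2-Ab1 45.9-fold (12.6 to 382), each on few NORM UMIs and in 8 of 8 libraries. Egln1, an oxygen sensor of the HIF pathway, rose by 1.28 ± 0.25. Among the genes that fell were Tagln3 (-0.88 ± 0.19, 1.37 ± 0.184 to 0.673 ± 0.169), 1110058L19Rik (-0.87 ± 0.19) and the pseudogenes Rps10-ps1 (-0.96 ± 0.21) and Gm10036 (-1.77 ± 0.40), of which Gm10036 is unusually high in the whole-retina NORM library at P14. In total 50 of 6967 genes passed (44 higher, 6 lower), and 1171 had an unadjusted p below 0.05. Matk, Hk2, Selenbp1, Pfkp, Pdk1, Bnip3, Aldoc, Vegfa, A2m, H2-Ab1 and H2-K1 passed whichever library was left out, whereas the 4 named lower genes held in at most 2 of 12 such fits. Ldha, Egln1 and Stat3 were lost without the rod-depleted OIR library at P17 (count 24) and without 1 of the whole-retina NORM libraries or more, Ldha and Egln1 also without rod-depleted NORM at P14, and Egln1 and Stat3 without whole-retina OIR replicate 2 at P17. The count fell to 21 without the rod-depleted NORM library at P14, to 30 without rod-depleted OIR replicate 1 at P14, and to 30 and 23 without the P17 whole-retina OIR replicates. It rose to 91 without the whole-retina NORM library at P14. At 300 UMIs per cell, a setting chosen after seeing the data, it was 12. At P17 the cluster led by Vstm2b and Il1rap held 84.8% of OIR and 2.22% of NORM rod-bipolar-like cells in whole retina, but 17.4% and 34.8% in rod-depleted retina.

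By lists, rod-bipolar-like cells had higher hypoxia and HIF targets (18 members, median 0.65, 6 past over all genes and 10 over the list alone, adjusted p = 3.2e-10) and higher interferon and antigen presentation (4, median 0.93, 2 and 3, adjusted p = 3.3e-05). Both held with an estimated correlation (adjusted p = 0.0020 and 0.028). Glycolysis was higher (18, median 0.21, 4 past over all genes and 8 up with 1 down over the list alone, adjusted p = 9.1e-05, 0.288 with an estimated correlation). Against this, the nuclear-encoded respiratory chain was lower (21, median -0.40, 0 and 7, adjusted p = 2.5e-08, 0.26 with an estimated correlation), with Ndufa4 from 27.0 ± 9.63 to 14.3 ± 3.06 (-0.75 ± 0.18, adjusted p = 0.064), Cox6a1 (-0.49 ± 0.14) and Atp5g1 (-0.71 ± 0.22). Ribosomal protein genes were lower (71, median -0.35, 0 past, adjusted p = 3.2e-10, 0.413 with an estimated correlation). Reactive gliosis genes (5, median 0.62, 2 and 3, adjusted p = 0.0042, 0.10 with an estimated correlation), angiogenesis genes (4, median 0.59, 1 and 2, adjusted p = 0.0067, 0.10 with an estimated correlation) and immediate early genes led by Jun (14, median 0.33, 0 and 3, adjusted p = 0.020, 0.413 with an estimated correlation) were higher, and Müller homeostasis genes lower (10, median -0.32, 0 and 1, adjusted p = 0.043, 0.413 with an estimated correlation).

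In cone-bipolar-like cells 11 genes rose and none fell. Hk2 rose by 2.36 ± 0.30 (adjusted p = 0.00055, 0.107 ± 0.138 to 1.41 ± 0.711), Selenbp1 by 2.17 ± 0.26, the metal-binding Mt1 by 1.74 ± 0.25, the hypoxic cytochrome oxidase subunit Cox4i2 by 1.66 ± 0.29, Bnip3 by 1.43 ± 0.23 (2.42 ± 0.902 to 7.05 ± 1.95) and Pfkp by 1.21 ± 0.19 (9.23 ± 4.12 to 20.6 ± 5.34, 7 of 8). H2-K1 rose by 1.62 ± 0.27. H2-Ab1, at 0 UMIs in NORM, was at least 13.3-fold higher (adjusted p = 0.032), and Loxl2 was 14.2-fold higher (4.79 to 69.8). Apart from Pfkp, each had 8 of 8 OIR libraries above NORM. Of 7845 genes 11 passed, and 792 had an unadjusted p below 0.05. Hk2, Selenbp1, Mt1 and Pfkp passed whichever library was left out. The count was 4 without the rod-depleted NORM library at P14, which H2-K1 needs, 7 without the whole-retina NORM library at P14 and 6 without the rod-depleted OIR library at P17. Bnip3 and Cox4i2 were lost without any of those 3, Loxl2 held in 7 of 12 fits and H2-Ab1 in 3.

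**Figure D2:**
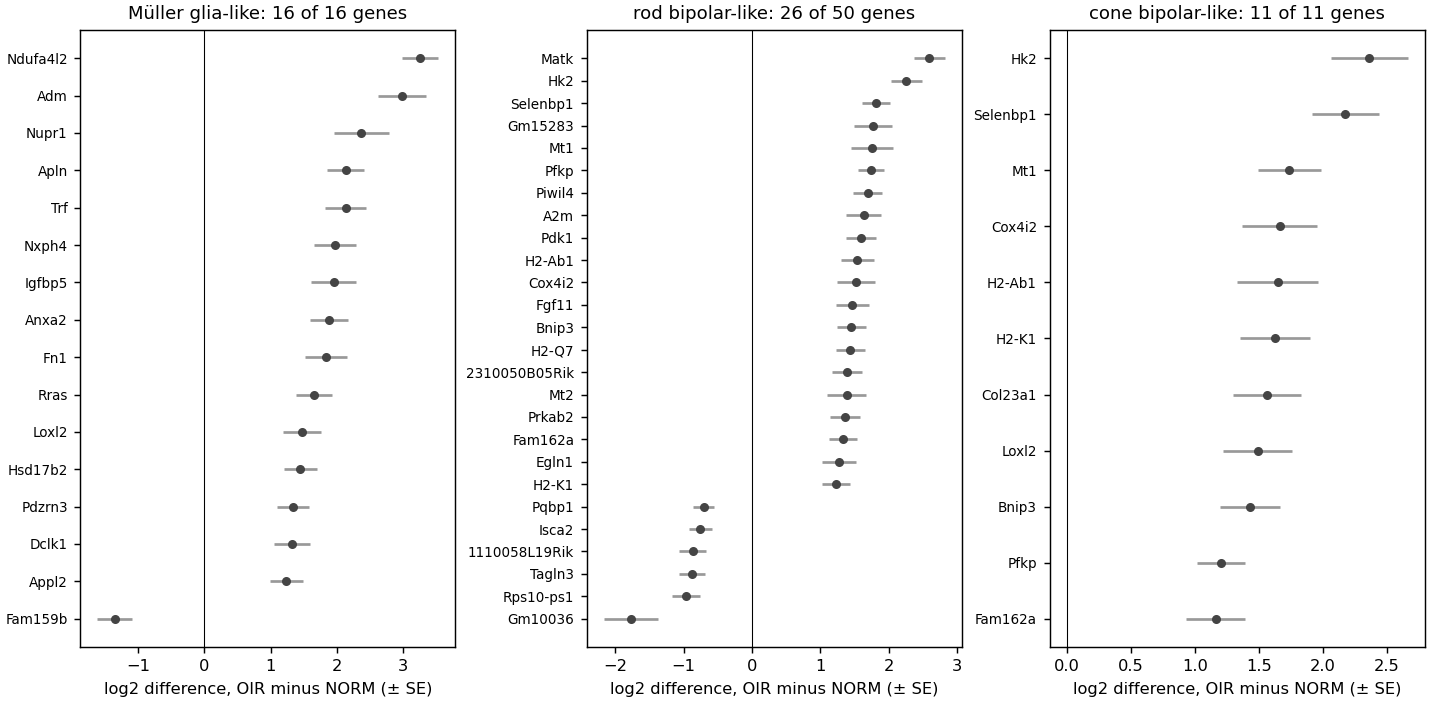
Log2 differences between OIR and NORM with standard errors for called genes of Müller-like (16 of 16), rod-bipolar-like (26 of 50) and cone-bipolar-like cells (11 of 11). Hk2 is at 2.25 in rod-bipolar-like and 2.36 in cone-bipolar-like cells.

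Hypoxia and HIF targets were higher in cone-bipolar-like cells (18 members, median 0.73, 2 past over all genes and 10 over the list alone, adjusted p = 2.6e-10, and 0.0037 with an estimated correlation), including P4ha2 (1.06 ± 0.23), as was interferon and antigen presentation (6, median 0.67, 2 and 3, adjusted p = 6.9e-05, 0.019 with an estimated correlation). Glycolysis (18, median 0.32, 2 and 6, adjusted p = 0.00023, 0.161 with an estimated correlation) held the lactate carrier Slc16a3 (1.44 ± 0.33, 8 of 8), and the barrier list the glucose carrier Slc2a1 (0.96 ± 0.21) and Bsg (0.73 ± 0.20; 4 members, median 0.59, 0 and 2, adjusted p = 0.0053, 0.169 with an estimated correlation). Immediate early genes were higher (13, median 0.46, 0 and 4, adjusted p = 0.0014, 0.161 with an estimated correlation), with Ier2 at 1.03 ± 0.28. Lower were the respiratory chain (21, median -0.22, adjusted p = 0.0014, 0.458 with an estimated correlation), Müller homeostasis (11, median -0.42, adjusted p = 0.019, 0.161 with an estimated correlation), rod phototransduction (22, median -0.31, adjusted p = 0.0050, 0.588 with an estimated correlation) and ribosomal proteins (74, median -0.18, adjusted p = 0.00018, 0.588 with an estimated correlation), each with 0 genes past over all genes. Rod phototransduction turned around without the whole-retina NORM library at P17.

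In microglia-like cells of OIR retina 12 genes rose and 2 fell. Haem oxygenase 1 (Hmox1) rose by 3.38 ± 0.40 (adjusted p = 7.5e-13), from 1.29 ± 0.058 (n = 2) to 14.9 ± 9.98 (n = 5), and ferritin heavy chain (Fth1) by 1.46 ± 0.22 (adjusted p = 7.0e-08), from 53.7 ± 16.1 to 141 ± 31.9. Osteopontin (Spp1), a gene of activated microglia, was 53.5-fold higher (95% counting interval 18.2 to 260, adjusted p = 1.2e-10, 4 of 5 libraries). Spp1 stood at 16.4 and 56.3 per 10000 in OIR at P14 but at 1.32, 0.224 and 1.67 in OIR at P17, against 0.128 and 0.593 in NORM. The elastase Mmp12, with 0 UMIs in NORM, was at least 21.8-fold higher (adjusted p = 6.0e-08, 5 of 5). The lipid carrier Fabp5 was 29.0-fold higher (5.10 to 1156) and the lactate carrier Slc16a3 17.9-fold (3.11 to 718). Lgals3 rose by 2.63 ± 0.52, Lpl by 1.73 ± 0.44 and Prdx1 by 1.49 ± 0.37. The protease inhibitor Cst3 fell from 264 ± 10.5 to 181 ± 55.7 (-0.87 ± 0.19) and Serinc3 by 1.44 ± 0.33, each below NORM in 5 of 5. Il1b did not pass (0.92 ± 0.37, adjusted p = 0.695), nor did Selplg (-1.03 ± 0.35) or the homeostatic Siglech (-0.72 ± 0.38).

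In microglia-like cells 14 of 6812 genes passed, and 402 had an unadjusted p below 0.05. These small p-values lean on the spread over all genes, with 3 degrees of freedom of a gene's own and 1283 borrowed ones. At 300 UMIs per cell, where 5.68 were borrowed, 0 passed. Hmox1 also leads 1 of the 2 microglia-like clusters, so that its level depends in part on the mix of clusters. The microglia-like result rests on 2 NORM libraries, both rod-depleted. Without the one at P14 the count was 0, and Hmox1, Mmp12, Spp1, Lgals3, Fabp5 and Fth1 were all lost. Without rod-depleted OIR replicate 2 at P14 it was 3, with Spp1, Lgals3 and Fabp5 lost. It was 6 without rod-depleted NORM at P17 (Fth1 lost), 5 without rod-depleted OIR at P17 (Fabp5 and Fth1 lost) and 7 and 8 without the P17 whole-retina OIR replicates. Serinc3 held in 3 of 7 such fits, Lpl, Prdx1 and Cst3 in 1 and Slc16a3 in 0. Where such a fit leaves a single NORM library, that lone library is assumed to vary like the others. Lists that were higher were microglial activation (15 members, median 0.72, 4 past over all genes and 7 over the list alone, adjusted p = 0.00011, 0.433 with an estimated correlation), antioxidant and metal genes (17, median 0.87, 3 and 6, adjusted p = 0.00051, 0.433 with an estimated correlation), glycolysis (16, median 0.95, or 0.92 with a gene at its bound, 1 and 6, adjusted p = 0.00011, 0.433 with an estimated correlation), hypoxia targets (18, median 0.54, 1 and 1, adjusted p = 0.0064, 0.434 with an estimated correlation), cell division (12, median 0.90, or 0.80 with a gene at its bound, 0 past, adjusted p = 0.0067, 0.512 with an estimated correlation) and haemoglobin (4, median 1.52, 0 and 1, adjusted p = 0.019, 0.50 with an estimated correlation). Of the haemoglobin genes Hbb-bs lay above NORM in 2 of 5 libraries and below it in 3, and Hbb-bs and Hba-a2 turned negative with at least 10 cells per library, Hba-a2 also without rod-depleted NORM at P14. Microglial homeostasis (10, median -0.44, 0 and 1, adjusted p = 0.025, 0.434 with an estimated correlation), rod phototransduction (21, median -0.45, 0 and 2, adjusted p = 0.0074, 0.433 with an estimated correlation) and cone phototransduction (9, median -0.67, 0 past, adjusted p = 0.025, 0.433 with an estimated correlation) were lower.

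In pericyte-like cells of OIR retina the highest calls included division genes and chemokines. The division genes Top2a, 2810417H13Rik and Prc1, with 0 UMIs in NORM (n = 2), were at least 11.7-fold, 12.6-fold and 8.53-fold higher in OIR (n = 3; adjusted p = 0.0012 each). Tyms was at least 5.91-fold higher, Ube2c 5.80-fold and RP23-45G16.5 4.61-fold. The chemokine Ccl2 was 15.1-fold higher (95% counting interval 4.12 to 126), Map2k2 16.4-fold (2.87 to 654) and Aebp1 between 2.26-fold and 519-fold by the same interval. Cxcl1 rose by 2.30 ± 0.41 (1.97 ± 1.68 to 11.4 ± 7.57), Hmgb2 by 2.52 ± 0.47, S100a6 by 2.11 ± 0.33 (3.24 ± 1.54 to 16.6 ± 8.49), Rps2 by 1.95 ± 0.34 and Vim by 1.36 ± 0.26 (8.68 ± 2.51 to 25.6 ± 8.90). The transporter Atp13a5 fell by 2.75 ± 0.57, Rgs3 by 2.82 ± 0.58, Col28a1 by 2.74 ± 0.62 and Atp2a3 by 2.68 ± 0.52, and Sfrp2 was 26.4-fold higher in NORM (5.46 to 251). Neuronal and rod genes fell as well: Snap25 by 3.23 ± 0.54, Gngt1 by 2.55 ± 0.54, Sncb by 2.59 ± 0.58, Scgn by 2.63 ± 0.62 and Sphkap by 2.58 ± 0.62. Every one of these genes had 3 of 3 OIR libraries beyond both NORM libraries.

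In pericyte-like cells 73 of 6882 genes passed (46 higher, 27 lower), and 1068 had an unadjusted p below 0.05. The fit had 2 degrees of freedom of a gene's own and 21.3 borrowed ones. In simulated data its false calls exceeded the share that the threshold allows, so some of the 73 may be false. The cells came from 5 rod-depleted libraries with 37 to 115 cells each. Median UMIs of these cells were 751 and 1176 in NORM and 2326 to 2928 in OIR, and Sag, a rod gene, stood at 0.849 and 4.50 per 10000 in NORM at P14 and P17 and at 0.0649 to 0.632 in OIR. With every cell at 300 UMIs, a setting chosen after seeing the data, the count was 20. Leaving out a P17 library raised it, to 573 without NORM and 483 without OIR; elsewhere it was 60 to 69. Map2k2, S100a6, Cxcl1 and Rps2 kept their calls throughout, and Top2a, Prc1 and 2810417H13Rik in the 2 fits that measured them. Without the rod-depleted NORM library at P14, Ccl2, Ube2c, Tyms, RP23-45G16.5, Hmgb2, Vim, Snap25, Rgs3, Atp13a5, Atp2a3, Sncb, Gngt1, Sfrp2 and Scgn were lost. Without rod-depleted OIR replicate 1 at P14 Col28a1, Sphkap, Sfrp2 and Scgn were lost, and without replicate 2 Aebp1, Sphkap, Sfrp2 and Scgn.

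Cell division genes had the smallest p of the pericyte-like lists (18 members, median 2.17, or 1.71 with 11 genes at their bounds, 7 past over all genes and 15 over the list alone, adjusted p = 5.2e-15, but 0.509 with an estimated correlation). NF-kB and cytokine genes (9, median 1.51, or 1.42 with bounds, 2 and 5, adjusted p = 0.00033), reactive gliosis (13, median 0.71 with 2 genes at their bounds, 2 and 4, adjusted p = 0.00040) and senescence factors (22, median 0.84, 3 and 7, adjusted p = 0.00091) were higher. Rod phototransduction (10, median -1.27, 1 and 5, adjusted p = 3.9e-05), cone phototransduction (11, median -1.59, 0 and 6, adjusted p = 3.9e-05), synapse genes (10, median -1.03, 1 and 3, adjusted p = 0.0014) and mitochondrially encoded genes (10, median -0.81, 1 and 6, adjusted p = 0.0019), with mt-Rnr2 from 71.0 ± 13.8 to 30.7 ± 9.75 (-1.34 ± 0.22), were lower. None of these pericyte-like lists passed with an estimated correlation (adjusted p = 0.509 for each). Ribosomal proteins were higher (77, median 0.49, 1 and 8, adjusted p = 0.00040, 0.558 with an estimated correlation).

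Few genes passed in the remaining classes. In cone-like cells the dopamine receptor Drd4 rose by 2.23 ± 0.39 (adjusted p = 0.018), from 0.418 ± 0.436 (n = 4) to 2.56 ± 1.31 (n = 8), in 8 of 8 libraries, as the 1 call among 6903 genes (620 at an unadjusted p below 0.05). That call was lost without rod-depleted NORM, rod-depleted OIR replicate 1 or whole-retina OIR replicate 1 at P14, or rod-depleted OIR or whole-retina OIR replicate 1 at P17, and the count was 33 without whole-retina NORM at P14. In ganglion-like cells the transcription factor Junb rose by 3.15 ± 0.62 (adjusted p = 0.023), from 0.178 ± 0.252 (n = 2) to 2.62 ± 1.42 (n = 6), the 1 call of 7887 genes (823 at an unadjusted p below 0.05). Junb was lost without rod-depleted OIR replicate 2 at P14, or without rod-depleted NORM, rod-depleted OIR or whole-retina OIR replicate 1 at P17. The ganglion-like count was 444 without rod-depleted NORM at P14, 4 without rod-depleted OIR replicate 2, and 2 without whole-retina OIR replicate 2 or 3 at P14, rod-depleted OIR or whole-retina OIR replicate 2 at P17. Horizontal-like cells had higher Pcsk1n (2.66 ± 0.47, adjusted p = 0.0053, yet only 1 of 4 libraries above NORM), the splicing cyclin Ccnl2 (2.54 ± 0.50, 1.07 ± 0.784 to 4.78 ± 2.99) and D4Wsu53e (1.53 ± 0.29, 8.45 ± 0.368 to 20.9 ± 6.21), 3 of 6983 genes (803 at an unadjusted p below 0.05). All 3 were lost without rod-depleted NORM or OIR replicate 2 at P14, or rod-depleted NORM or OIR at P17.

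No gene passed in amacrine-like cells (0 of 8179, with 772 at an unadjusted p below 0.05 and 3 by voom) or rod-like cells (0 of 6907, with 909 and 5). In amacrine-like cells the lowest p-values belonged to the metal-binding Mt2 (1.63 ± 0.30, adjusted p = 0.17, 6 of 8), Gm10036 (-1.72 ± 0.35), Mt1 (1.31 ± 0.28, adjusted p = 0.27) and Pttg1 (1.33 ± 0.29), the last of which is low in whole-retina NORM at P14. Without that library 2 genes passed, 1 without whole-retina NORM at P17 and 2 without whole-retina OIR replicate 1 at P17. In rod-like cells they were 1700029J07Rik (1.76 ± 0.25, adjusted p = 0.13), Pfkp (1.47 ± 0.27, adjusted p = 0.36, 2.21 ± 0.935 in 3 NORM to 5.96 ± 1.25 in 5 OIR libraries, all 5 above), Gm16055 and A430035B10Rik (1.31 ± 0.26). Leaving out whole-retina NORM at P14 gave 1802 calls in rod-like cells and whole-retina NORM at P17 gave 12. At P17, 92.0% of OIR rod-like cells lay in the cluster led by Guca1b and Nrl and 96.3% of NORM ones in a cluster led by Nr2e3 with a median of 374 UMIs.

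Immediate early genes were higher in amacrine-like cells (13 members, median 0.74, 0 past over all genes and 5 over the list alone, adjusted p = 3.2e-06, 0.22 with an estimated correlation), with Egr1 at 0.88 ± 0.28 and Fosb at 0.90 ± 0.32. Also higher there were interferon genes such as H2-D1 (0.86 ± 0.23, 8 of 8; 6, median 0.68, 0 and 2, adjusted p = 0.0065, 0.156 with an estimated correlation), hypoxia targets (18, median 0.34, adjusted p = 0.0088, 0.156 with an estimated correlation) and haemoglobin (4 members, 0 and 1, adjusted p = 0.0065, 0.44 with an estimated correlation). The haemoglobin genes exceeded NORM in 3 of 8 libraries, all 4 were lower in the rod-depleted same-run pair (-0.98 to -2.27), and Hba-a1, Hbb-bs and Hba-a2 turned negative at both other resolutions, with no filter on cells, with at least 500 genes per cell and in rod-depleted libraries only. Cone phototransduction was lower (11, median -0.75, 0 and 4, adjusted p = 3.1e-06, 0.156 with an estimated correlation; Opn1mw -1.31 ± 0.31), as were cholesterol genes led by Hmgcs1 (-0.74 ± 0.21; 14, median -0.47, adjusted p = 0.00039, 0.156 with an estimated correlation), ribosomal proteins (73, median -0.35, adjusted p = 7.0e-10, 0.44 with an estimated correlation), the respiratory chain (21, median -0.29, adjusted p = 0.0020, 0.44 with an estimated correlation), Müller homeostasis (11, median -0.25, adjusted p = 0.0073, 0.31 with an estimated correlation), rod phototransduction (22, median -0.28, adjusted p = 0.0065, 0.56 with an estimated correlation) and mitochondrially encoded genes (10, median -0.23, adjusted p = 0.025, 0.56 with an estimated correlation). The last 2 turned around without whole-retina NORM at P17.

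Ganglion-like cells had higher immediate early genes (14 members, median 1.29, 1 past over all genes and 2 over the list alone, adjusted p = 0.00058, 0.315 with an estimated correlation), Junb and Nr4a1 (1.91 ± 0.67) in front, and higher haemoglobin (4, median 2.55, 0 and 4, adjusted p = 2.5e-05, 0.315 with an estimated correlation), where Hbb-bs lay above NORM in 3 of 6 libraries and below it in 3. Their glycolysis genes were lower, among them Tpi1 (-1.22 ± 0.40) and Gapdh (-2.20 ± 0.73; 18, median -0.23, 0 and 2, adjusted p = 0.024, 0.315 with an estimated correlation). Also lower in ganglion-like cells were cone phototransduction (7, median -1.44, 0 and 3, adjusted p = 6.5e-05, 0.315 with an estimated correlation), ribosomal proteins (67, median -0.57, 0 and 4, adjusted p = 2.2e-06, 0.391 with an estimated correlation), the respiratory chain (21, median -0.37, adjusted p = 0.044, 0.315 with an estimated correlation), Müller homeostasis (11, median -0.55, adjusted p = 0.024, 0.391 with an estimated correlation) and rod phototransduction (21, median -0.12, adjusted p = 0.024, 0.449 with an estimated correlation). Rod-like cells had lower ribosomal proteins (71, median -0.64, 0 and 1, adjusted p = 1.3e-18), respiratory chain (21, median -0.46, adjusted p = 2.5e-05) and mitochondrially encoded genes (10, median -0.77, 0 and 7, adjusted p = 1.5e-05; mt-Nd1 -1.05 ± 0.29) and higher gliosis genes led by Stat3 (0.78 ± 0.26; 6, median 0.45, 0 and 2, adjusted p = 0.025), all with 0.499 for an estimated correlation. Their cone phototransduction genes were lower (12, median -0.43, adjusted p = 0.016, 0.604 with an estimated correlation) but turned around without whole-retina NORM at P17. Horizontal-like cells had higher interferon genes, such as H2-K1 (1.97 ± 0.64; 4, median 1.76, 0 and 3, adjusted p = 0.015), and lower ribosomal proteins (67, median -0.55, adjusted p = 0.00033), both with 0.975 for an estimated correlation. Cone-like cells had lower ribosomal proteins (71, median -0.26, adjusted p = 8.2e-05, 0.856 with an estimated correlation).

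Across classes, 73 list calls were made and 4 held with an estimated correlation: hypoxia targets and antigen presentation in both kinds of bipolar-like cell. The BCL2 family and apoptosis list passed in none of 10 classes (medians -0.20 to 0.20, smallest adjusted p 0.464), nor did heat shock genes (-0.29 to 0.48, 0.181), the unfolded protein and integrated stress response (smallest 0.132), complement (3 classes, 0.178 to 0.441), crystallins (amacrine-like cells only, median 0.64, 0.136) or the sex chromosome check (7 classes, smallest 0.647). Genes of neutrophils and extracellular traps never reached 4 measured members.

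Of the genes fixed for every class, Vegfa was measured in 10 and passed in rod-bipolar-like cells alone. Its difference ran from -0.94 in pericyte-like cells to 1.27 in Müller-like cells, positive in 9 classes and with an unadjusted p below 0.05 in 5; in cone-bipolar-like cells it was 1.10 ± 0.27 (7 of 8 libraries). The senescence gene Cdkn1a passed in 0 of 7 classes, with the largest difference in amacrine-like cells (1.45 ± 0.33, adjusted p = 0.269, 7 of 8) and 6 of 7 positive. The survival gene Bcl2l1 passed in 0 of 10 classes, from -0.38 in horizontal-like to 0.52 in ganglion-like cells, with 0 at an unadjusted p below 0.05. Hmox1 passed in microglia-like cells but not in Müller-like cells (0.0097 ± 0.38). Edn2, an injury signal of photoreceptors, had 0 UMIs in NORM rod-like cells and 0.467 ± 0.295 per 10000 in 5 of 5 OIR libraries (adjusted p = 0.362).

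**Figure D3:**
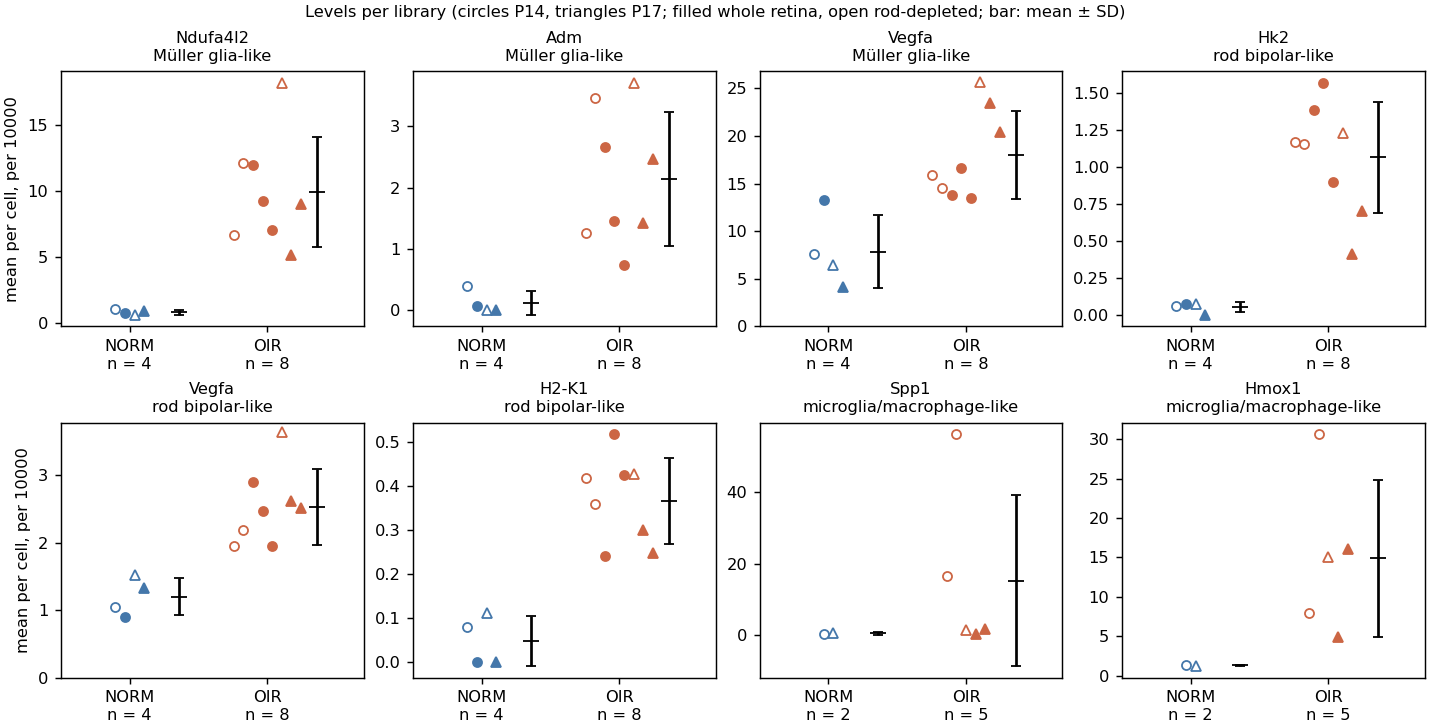
Levels per 10000 of 8 genes in the class named above each panel, with 1 point per library, NORM against OIR, and bars for the mean and SD. Ndufa4l2 of Müller-like cells reaches a mean of 9.95 in OIR, and all 8 OIR libraries are above NORM.

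Rod RNA reached other classes in whole retina. Müller-like cells held Sag at 11.3 ± 10.9 per 10000 in whole-retina NORM (n = 2) and 3.99 ± 1.45 in whole-retina OIR (n = 5), against 1.46 ± 1.76 (n = 2) and 0.482 ± 0.262 (n = 3) after depletion. The NORM mean rests on the P17 library (19.0, against 3.63 at P14), so that it gives no difference between OIR and NORM. Gnat1 in whole-retina NORM was 12.3 at P17 and 0.766 at P14 in Müller-like cells, 12.1 and 1.09 in rod-bipolar-like, 12.6 and 1.31 in cone-bipolar-like and 13.2 and 0.626 in amacrine-like cells, and each OIR mean lay between the 2 values (1.82 ± 0.876, 3.75 ± 1.41, 2.93 ± 0.742 and 2.47 ± 0.720). After depletion Gnat1 of Müller-like cells was 0.112 ± 0.133 and 0.0707 ± 0.0152. Rod-like cells themselves held Sag at 188 ± 46.4 in NORM and 148 ± 9.76 in OIR, and Gnat1 at 81.2 ± 27.9 and 76.6 ± 6.94. Rod genes outside rod-like cells are therefore not read as expressed there. Nor are cone and Müller homeostasis genes in other classes, whose carry-over was not tested.

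Within the 2 same-run pairs at P14 the called genes kept their direction, save Loxl2 of Müller-like cells in whole retina (-0.050). In rod-depleted retina this held for 16 of 16 genes of Müller-like cells, 50 of 50 of rod-bipolar-like, 11 of 11 of cone-bipolar-like, 14 of 14 of microglia-like and 73 of 73 of pericyte-like cells; in whole retina for 15 of 16, 50 of 50 and 11 of 11 in the first 3. Igfbp5 of Müller-like cells had 2.03 in the rod-depleted pair but 0.12 in whole retina. Several genes that did not pass turned, among them Nes (-0.23) and Nfkbiz (-0.57) of Müller-like cells in whole retina and Egr1 (-0.34) and Fosb (-0.69) of amacrine-like cells in rod-depleted retina. Medians of the higher genes in the rod-depleted and whole-retina pair against the pooled fit were 1.99 and 1.54 against 1.88 in Müller-like, 1.26 and 1.32 against 1.20 in rod-bipolar-like and 1.66 and 1.76 against 1.62 in cone-bipolar-like cells. Microglia-like cells had 2.76 against 2.63, pericyte-like cells 2.72 against 2.37, Drd4 of cone-like cells 2.29 and 1.98 against 2.23, Junb of ganglion-like cells 1.78 against 3.15 and the 3 horizontal-like genes 1.31 against 2.54. These pairs took part in the pooled fit, and 53.0% to 81.8% of all genes kept their direction.

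Between P14 and P17, Müller-like cells changed most (41 of 105 calls over all classes, 14 higher at P17 and 27 lower). Proline dehydrogenase (Prodh) was higher at P17 by 1.60 ± 0.24 (adjusted p = 0.0087), with Fxyd6 (1.56 ± 0.32), the long non-coding Neat1 (1.33 ± 0.29) and Ifit3 (1.31 ± 0.27). The activity genes Nr4a3 (-2.31 ± 0.36), Ifrd1 (-2.12 ± 0.28, adjusted p = 0.0033), Atf3 (-2.03 ± 0.40) and Irf1 (-1.90 ± 0.42) were lower. Cone-bipolar-like cells had 28 calls and rod-like cells 11. No stated run holds libraries of both ages. Only Prodh, Nr4a3 and Ifrd1 passed whichever library was left out. The total ran from 36 and 52 without whole-retina OIR replicate 2 or 1 at P17 to 358 without rod-depleted OIR at P17, with 302 without whole-retina NORM at P17, 189 without whole-retina NORM at P14, 59 without rod-depleted OIR replicate 2 at P14, and 44 and 63 without whole-retina OIR replicates 2 and 3 at P14.

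At P14 alone 42 genes passed over all classes: 20 in rod-bipolar-like cells, 12 in rod-like cells, 5 in Müller-like cells (Ndufa4l2, Trf, Nupr1, Ptgds and Adm, with Trf low in the whole-retina NORM library at P14), 4 in cone-bipolar-like cells (Selenbp1, Bnip3, Hk2 and Mt1) and Spp1 in microglia-like cells. The rod-like ones include Rpl3, Hspa8, Rps3a1, Gm10036 and Rps3a3, which the whole-retina NORM library at P14 alone sets apart, and the total fell to 7 without that library and rose to 74 without rod-depleted OIR at P17. For the results per age, ganglion-like cells had 1 NORM library at each age. The one at P17 held 23 cells with a median of 596 UMIs, against 1872 to 2915 UMIs in OIR at P17. At P17 2633 genes passed over all classes, 1817 of them in rod-like and 453 in ganglion-like cells, with 145 in Müller-like and 163 in rod-bipolar-like cells. That total was 481 without whole-retina NORM, 10336 without rod-depleted NORM, and 880 and 948 without the whole-retina OIR replicates, all at P17.

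The difference between OIR and NORM changed with age in 856 genes, tested as an interaction: 718 in rod-like, 128 in ganglion-like, 7 in Müller-like and 3 in amacrine-like cells. In rod-like cells the clock gene Cry1 (3.88 ± 0.45, adjusted p = 0.0011), Pex5l (3.81 ± 0.40), GM20417 (3.69 ± 0.54) and Fnbp4 (3.65 ± 0.40) had the highest values. Rpl3 (-5.54 ± 0.37, adjusted p = 2.2e-05), Gm10288 (-4.06 ± 0.45), Ndufs5 (-4.04 ± 0.60) and Hspa8 (-4.02 ± 0.38) had the lowest; Rpl3, Ndufs5 and Hspa8 are low in whole-retina NORM at P14, and Pex5l leads the cluster that holds most OIR rod-like cells at P17. In Müller-like cells Atf3, Socs3, Maff, Ddit3, Coq10b, Pdcd4 and Egr2 passed. The interaction total was 134 without whole-retina NORM at P14, 133 without whole-retina NORM and 4786 without rod-depleted NORM at P17, and 214 and 243 without the whole-retina OIR replicates at P17. Median UMIs of rod-like cells at P17 were 336.5 in NORM and 1070 and 1106 in OIR. Ganglion-like cells at P17 had 596 in their 1 NORM library and 1872 to 2915 in OIR. Interaction values of rod-like and ganglion-like cells therefore cannot be told from depth. With every cell at 300 UMIs the totals over all classes were 1406 at P17 and 394 for the interaction.

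Positions are those of GRCm38 with GENCODE release M21. Ndufa4l2 lies on chromosome 10 at 127514967-127517154 (+), Adm on 7 at 110627661-110629820 (+), Apln on X at 48025146-48034853 (-), Gfap on 11 at 102887336-102900912 (-) and Vegfa on 17 at 46016993-46032369 (-). Matk lies on 10 at 81252935-81263365 (+), Hk2 on 6 at 82725025-82774454 (-), Pfkp on 13 at 6579768-6648777 (-), Selenbp1 on 3 at 94933056-94944758 (+), Bnip3 on 7 at 138890836-138909519 (-), H2-K1 on 17 at 33996017-34000347 (-) and Tagln3 on 16 at 45711230-45724608 (-). Hmox1 lies on 8 at 75093621-75100589 (+), Spp1 on 5 at 104435118-104441050 (+), Mmp12 on 9 at 7344381-7369499 (+) and Fth1 on 19 at 9980598-9985098 (+). Top2a lies on 11 at 98992943-99024189 (-), Drd4 on 7 at 141292006-141296464 (+) and Junb on 8 at 84974484-84978718 (-). All are protein-coding, while Gm10036 (18, 15832794-15833327, +) is a processed pseudogene.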

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

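Chosen only after the result was seen were the comparison of classes within the whole-retina NORM library at P14, both tests of the lens crystallins and the thinning to 300 UMIs; the other tests were planned.

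Among the 5 rod-depleted libraries, amacrine-like cells were 4.14% in OIR replicate 1 at P14, far below the nearest library (8.35%), and rod-like cells 1.52% in NORM at P17, far above the nearest (0.464%). These are 2 of 43 groups tested for a sample far from the rest, where chance alone gives about 1 in 20. A difference between groups marked the counts of genes whose response changed with age: 7 in Müller-like, 3 in amacrine-like, 128 in ganglion-like and 718 in rod-like cells. A signal outside the main comparisons marked the crystallin-led cells of whole-retina OIR replicates 2 and 3 at P14, 380 and 314 cells, against 0 in the other libraries.

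In the whole-retina NORM library at P14, 8 genes (Pttg1, Rpl3, Rps3a1, Hspa8, Trf, Acp1, Ndufs5 and Hmgb1) lay far below the lowest other library, with Rpl3 at 0.0962 per 10000 against 2.57 and Hspa8 at 0.564 against 8.06, while the copies Rps3a3 (4.50 against 0.756) and Gm10036 (3.80 against 0.616) and the gene Gdpd3 were high. Of the 31-base words in the last 400 bases of the 8 genes, a median of 55.4% also occurs in another gene, against 4.22% at the 95th percentile of random lists, and 7 of the 8 exceed 20%. Reads shared with near-identical copies and assigned differently in this library may thus account for those 7; Pttg1 shares none. A different mix of cell types is excluded, since in 85.4% of pairs of gene and class the library stayed below 0.5 times the lowest other library. No biological explanation was tested, because the pattern is in a single library.

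The 380 and 314 crystallin-led cells came from the 2 libraries of a single run. Lens crystallins in their other cells stood at 7.04 and 6.57 per 10000, against at most 0.0926 in any other library, and in all 14 pairs of library and class they exceeded the highest other library of that class. Lens RNA or lens tissue carried into this run remains the open explanation. This comparison within classes replaced, after its result was seen, a comparison over all classes together, in which the lowest value here (1.49, ganglion-like cells) was below the highest elsewhere (1.96, microglia-like cells of rod-depleted NORM at P14). OIR as the reason is excluded, as the other 3 OIR libraries at P14 reached at most 0.880% of the lower of the 2.

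Hmox1, Spp1, Mmp12 and Fth1 were raised in microglia-like cells of OIR. A different mix of the 2 clusters is excluded as the whole reason. In the Ctss-led cluster (2 NORM and 3 OIR libraries) the 14 called genes kept their direction (median log2 size 2.28, 2.55 in the class). Sizes moved both ways: Hmox1 from 3.38 to 2.77 ± 0.48, Uqcrfs1 from 2.63 to 1.19 ± 0.92, Lgals3 from 2.63 to 5.11 ± 0.59. Cd74-led cells were 36.4% of NORM and 43.1% of OIR cells at P14, 54.4% and 48.4% at P17. UMIs per cell stay open as a reason, as thinning keeps a cell's expected proportions. At 300 UMIs Hmox1 had 3.48 ± 0.64, Fth1 1.40 ± 0.29, Mmp12 3.94 ± 1.05 and Spp1 3.23 ± 1.45. With all UMIs they had 3.38, 1.46, 4.01 and 4.14. The median over the 14 genes fell to 1.82. The calls ended at 300 UMIs (0 past, each adjusted p 0.999). The median standard error grew from 0.478 to 0.965, and borrowed degrees of freedom fell to 5.68. An effect of OIR on these cells stays open as a hypothesis, beside the foster mother and other differences of the design, which were not tested.

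Other splits into groups of the same sizes asked how often chance gives as many calls. The count for Müller-like cells was reached by 1 of 100 splits, the real one (16, highest other 4), for rod-bipolar-like cells by 1 of 100 (50, highest other 2) and for cone-bipolar-like cells by 2 of 100 (11, highest other 35). It was reached by 7 of 100 in cone-like cells (1, highest other 31), where chance is not excluded. In amacrine-like (0, highest other 103) and rod-like cells (0, highest other 1805) all 100 and all 55 splits reach 0 by design, which says nothing about chance. The age total over the 5 classes with all libraries (74) was reached by 3 of 100 (highest other 657), a share under 1 in 20. For lists (40, highest other 46) it was 5 of 100, where chance is not excluded. At P14 the best other splits swap rod-depleted NORM for whole-retina OIR replicate 1 in Müller-like and rod-bipolar-like cells and lists. In amacrine-like, cone-like and cone-bipolar-like cells they swap whole-retina NORM for rod-depleted OIR replicate 1. Near the real grouping, they cannot tell run dates from oxygen.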

How the results depend on the processing

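Of 383 named gene values under 42 settings, 117 are called genes and none of those changed direction; 161 values in 72 results changed direction, all of lists or of genes that did not pass. Called genes kept their side of the threshold in 1268 values and lost it in 440 under other settings, and in 616 and 344 with 1 library left out. Losses were most common in whole retina alone (38 of 45), in the 2 same-run pairs (22 of 34) and at 300 UMIs (74 of 110), which hold fewer libraries or UMIs. Fits with 1 library left out may leave a single NORM library and 1 residual degree of freedom, and they assume that it varies like the others. Voom stands in for the planned edgeR and DESeq2 tests. Genes low in UMIs pass only with large changes, and shallow libraries limit which genes are tested. Replicate numbers do not pair the libraries: correlations of deviations between libraries of the same number were 0.041, 0.114, 0.361, 0.361, -0.038 and -0.223. Chosen after seeing the data were voom, 300 UMIs, leaving out the run with crystallin-led cells, and the age result under settings not planned for it. Below, classes are named without "-like", values that moved are given, and the cause was not tested unless stated.

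Counts of called genes against the main 16 in Müller, 0 in amacrine, 1 in cone, 11 in cone bipolar, 3 in horizontal, 14 in microglia, 73 in pericyte, 1 in ganglion, 0 in rod and 50 in rod bipolar cells, 105 for age, 42 at P14, 2633 at P17, 856 for interaction and 73 lists moved as follows. With no filter on low genes, which tests more genes: Müller 3, cone 0, cone bipolar 1, horizontal 7, microglia 0, pericyte 155, ganglion 0, rod bipolar 17, age 23. With weights by number of cells: Müller 66, amacrine 5, cone 11, cone bipolar 24, horizontal 11, ganglion 0, rod 1, rod bipolar 276, age 770. With the same number of cells per library: Müller 26, cone 2, cone bipolar 7, horizontal 31, rod 7. In whole retina only: Müller 2, cone 0, cone bipolar 3, rod bipolar 3, age 27. In rod-depleted libraries only: amacrine 1, cone 2, cone bipolar 2, age 67. In the 2 same-run pairs at P14 with run as a block: Müller 44, cone 0, cone bipolar 0, rod bipolar 14. With a replicate block: Müller 4, cone bipolar 3, microglia 9, ganglion 0, rod bipolar 12, age 21, P14 11, P17 87, interaction 17, lists 47. With at least 500 genes per cell: Müller 29, amacrine 1, cone bipolar 7, microglia 4, rod bipolar 17. By voom: Müller 55, amacrine 3, cone 4, horizontal 8, pericyte 116, rod 5, age 1309. Without the 2 libraries of the run with crystallin-led cells: Müller 6, cone bipolar 6, ganglion 2, age 44, P14 17, P17 374, interaction 17. At 300 UMIs: amacrine 1, cone 3, cone bipolar 5, horizontal 0, microglia 0, pericyte 20, ganglion 2, rod bipolar 12, age 61, P17 1406, interaction 394, lists 46. At resolution 0.5: amacrine 1, cone bipolar 6; at resolution 2.0: amacrine 1. With no filter on cells: amacrine 1, horizontal 17, ganglion 4. With a pseudocount of 0.05: cone 0, horizontal 8, rod bipolar 33, age 50; with a pseudocount of 1: horizontal 0, microglia 7, pericyte 43, ganglion 5. With at least 10 cells per library: horizontal 13, pericyte 182, ganglion 0. Scaling without rod and mitochondrial genes gave horizontal 10, and quantile normalisation horizontal 12, microglia 6, ganglion 0. Without Scrublet doublets: horizontal 12, pericyte 120. With P17 libraries only, 4039 genes passed at P17. Lists numbered 4 by camera with an estimated correlation, 22 by fry in 1 direction and 37 by fry in mixed directions.

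With 1 library left out, counts ran from 7 (without rod-depleted OIR at P17) to 27 (whole-retina NORM at P14) in Müller, 0 to 2 in amacrine (whole-retina NORM at P14 or OIR replicate 1 at P17), 0 to 33 in cone (whole-retina NORM at P14), 4 (rod-depleted NORM at P14) to 14 in cone bipolar, 0 to 3 in horizontal, 0 (rod-depleted NORM at P14) to 14 in microglia, 60 to 573 (rod-depleted NORM at P17) in pericyte, 0 to 444 (rod-depleted NORM at P14) in ganglion, 0 to 1802 (whole-retina NORM at P14) in rod and 21 (rod-depleted NORM at P14) to 91 (whole-retina NORM at P14) in rod bipolar cells. Totals ran from 36 to 358 for age, 7 to 74 at P14, 481 to 10336 at P17, 133 to 4786 for interaction and 56 (rod-depleted OIR at P17) to 81 (rod-depleted OIR replicate 1 at P14) for lists. Class shares past the threshold stayed at 8 to 9 of 13 for rod depletion. They were 0 for OIR, which shows no stability, because too few arrangements exist for a single class to pass.

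Genes below did not pass in the main fit and changed sign; the value is the log2 difference under the setting. In rod-depleted libraries only: Unc5b -0.17, Bcl2l1 -0.40 and Hmox1 -0.23 in Müller; mt-Co1 0.058, mt-Nd5 0.017, H2-Ab1 -0.042, Hba-a1 -0.028, Hbb-bs -0.28 and Hba-a2 -0.53 in amacrine; Tjp1 -0.15, Itm2a -0.33 and Rps3a3 0.071 in cone bipolar and Aqp4 -0.13 in rod bipolar cells. In the 2 same-run pairs with run as a block: Sag 0.52, Guca1a 0.54, Gnb1 0.061, Pdc 0.80, Klf4 -0.027, Timp3 -0.22, Bcl2l1 -0.34 and Hmox1 -0.029 in Müller cells. In the same pairs amacrine cells had mt-Nd1 0.058, mt-Co1 0.66, mt-Rnr2 0.13, mt-Nd5 0.25, Spc25 0.55, Guca1a 0.0096, Sag 0.39, Rdh12 0.63, Pde6h 0.30, Hba-a1 -0.74 and Hbb-bs -0.90. Cone cells there had Rpl7 0.19 and Bcl2l1 -0.84, cone bipolar cells Uqcrh 0.098, Sox9 -0.014, Car2 0.037, Tjp1 -0.083, Rcvrn 0.078, Rpl7a 0.36 and Rps7 0.19, and rod bipolar cells Rlbp1 0.074, Col4a2 -0.62 and Rpl6 0.11. With at least 500 genes per cell: Gnb1 0.055, Pdc 0.061, Bcl2l1 -0.27 and Hmox1 -0.16 in Müller, Acsl3 0.089, Hba-a1 -0.69, Hbb-bs -0.071 and Hba-a2 -0.34 in amacrine, Bcl2l1 -0.14 in cone, Itm2a -0.17 in cone bipolar, Arr3 0.030 and Gnb3 0.67 in microglia, and Rlbp1 0.15 and Bcl2l1 0.24 in rod bipolar cells. At 300 UMIs: Bcl2l1 -0.025 in Müller, Glul 0.017, Gpr37 0.29 and Bcl2l1 0.20 in amacrine, Bcl2l1 0.43 in cone bipolar and 0.010 in rod bipolar, and Atp5o 0.83, Vegfa -1.13 and Cdkn1a 0.12 in ganglion cells. By voom: Bcl2l1 -0.48 and Hmox1 -0.51 in Müller, Spc25 0.23 and Rdh12 0.39 in amacrine, Bcl2l1 -0.065 in cone and -0.21 in rod, Itm2a -0.043 in cone bipolar, Col4a1 -0.017 in rod bipolar, and Atp5j 0.034, Vegfa -1.07, Cdkn1a 1.17 and Bcl2l1 -0.84 in ganglion cells.

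At resolution 0.5: Hba-a1 -0.82, Hbb-bs -0.29 and Hba-a2 -0.80 in amacrine, Tjp1 -0.11 in cone bipolar and Cdkn1a 0.015 in ganglion cells. At resolution 2.0: Hba-a1 -0.81, Hbb-bs -0.29 and Hba-a2 -0.79 in amacrine and Itm2a -0.10 in cone bipolar cells. With no filter on cells: Hba-a1 -0.61, Hbb-bs -0.34 and Hba-a2 -0.28 in amacrine, Cdkn1a 0.10 in ganglion and Bcl2l1 -0.13 in rod cells. With the same number of cells per library: Bcl2l1 -0.72 in Müller, 0.14 in amacrine, -0.21 in cone and 0.19 in rod bipolar, Rpl7 0.20 in cone, Stat3 -0.26 and Il6st -0.67 in rod, and Cdkn1a 0.080 in ganglion cells. By quantile normalisation: Bcl2l1 -0.065 and Hmox1 -0.27 in Müller, Itm2a -0.018 in cone bipolar, Cdkn1a 0.13 in ganglion and Bcl2l1 -0.084 in rod cells. With at least 10 cells: Rps3a1 0.73 in horizontal, Arr3 0.019, Sall1 0.18, Hbb-bs -0.52, Hba-a2 -1.04 and Bcl2l1 0.48 in microglia, and Pdc 0.29 in ganglion cells; with at least 50: Bcl2l1 -0.35 and Hmox1 -0.044 in Müller cells. With weights by cells: Bcl2l1 -0.23 and Hmox1 -0.12 in Müller, Cdkn1a 0.35 in ganglion and Bcl2l1 -0.0055 in rod cells. With a pseudocount of 1 Hmox1 had -0.0080 in Müller cells, and with 0.05 Cdkn1a 0.20 in ganglion cells, where scaling without rod and mitochondrial genes gave 0.0040. With a replicate block: Hmox1 -0.44 in Müller, Vegfa -0.49 in microglia and Bcl2l1 -0.14 in rod cells.

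Leaving out 1 library turned the following, given as lowest to highest value. Bcl2l1 ran from -0.35 to 0.47 in Müller, -0.19 to 0.015 in amacrine, -0.22 to 0.60 in cone, -0.67 to 0.084 in microglia, -0.62 to 0.0015 in pericyte, -0.70 to 1.74 in ganglion and -0.28 to 0.0052 in rod bipolar cells. Vegfa ran from -0.26 to 1.80 in horizontal, -0.79 to 0.78 in microglia, -2.53 to 1.19 in pericyte and -0.61 to 0.91 in ganglion cells, Hmox1 from -0.18 to 0.29 in Müller and Cdkn1a from -1.18 to 1.16 in ganglion cells. Rgs9 ran from -0.055 to 1.23 in amacrine, Tjp1 -0.13 to 0.75 and Itm2a -0.063 to 0.36 in cone bipolar, B2m -0.64 to 1.29 in horizontal, Slc2a1 -0.25 to 2.81 and Hba-a2 -0.027 to 0.81 in microglia, and Col4a2 -0.13 to 0.94 and Col4a1 -0.031 to 0.53 in rod bipolar cells. Adjusted p-values of 5 lists, with a minus sign where the list was lower, ran from -0.0538 to 0.277 (rod phototransduction in Müller), -0.0831 to 0.750 (mitochondrially encoded genes in amacrine), -0.128 to 0.411 (rod phototransduction in amacrine), -0.0820 to 0.9502 (rod phototransduction in cone bipolar) and -0.0949 to 0.9495 (cone phototransduction in rod cells), all turned without whole-retina NORM at P17.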

Other observations

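The tests of endothelial-like and astrocyte-like cells with at least 10 cells per library and the search for genes high in a single library were chosen only after the result was seen.

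In endothelial-like cells of OIR 11 genes fell and 7 rose. Bsg, a partner of lactate carriers, fell by 1.54 ± 0.23 (adjusted p = 0.00032), from 102 ± 14.1 per 10000 in 3 NORM to 35.9 ± 10.3 in 4 OIR libraries. The organic anion carrier Slco1a4 fell by 2.82 ± 0.47 (adjusted p = 0.0018), the lactate carrier Slc16a1 by 2.29 ± 0.42 (12.1 ± 1.23 to 3.12 ± 2.71), Spock2 by 1.92 ± 0.36, and Ly6c1 (2.33 ± 0.43) and Pltp (1.91 ± 0.36), which are leading genes of this cluster, fell too. Igfbp3 rose by 2.87 ± 0.54 (0.450 ± 0.420 to 4.21 ± 1.92), Prkcdbp by 2.99 ± 0.57, the division genes Top2a by 2.79 ± 0.59 and Mki67 by 2.54 ± 0.57, and Col18a1 by 2.06 ± 0.48. The division gene 2810417H13Rik was 40.3-fold higher (95% counting interval 6.86 to 1629). Of 7106 genes 18 passed (504 at an unadjusted p below 0.05), on 135 NORM and 108 OIR cells. Bsg held in 5 of 7 fits with 1 library left out and was lost without whole-retina NORM or whole-retina OIR replicate 3 at P14. Slco1a4 also needed rod-depleted NORM at P17, the other lower genes named rod-depleted OIR at P17 as well, Igfbp3 and Prkcdbp held in 2 of 7, and Top2a, Mki67 and Col18a1 in 0.

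Astrocyte-like cells of OIR had 5 higher genes of 6866 (688 at an unadjusted p below 0.05), on 39 NORM and 104 OIR cells in 2 and 5 libraries. The reactive marker Serpina3n was 48.3-fold higher (95% counting interval 13.3 to 400, adjusted p = 0.00022), Ier2 rose by 2.46 ± 0.38 (adjusted p = 0.00074), Jun by 1.78 ± 0.34 (11.9 ± 10.5 to 31.3 ± 13.2), Igfbp2 by 1.91 ± 0.37 (3.17 ± 1.10 to 13.3 ± 5.52) and Glycam1 by 3.13 ± 0.60. Serpina3n was lost without rod-depleted NORM at P14 or P17, Ier2 and Jun without these or rod-depleted OIR at P17, and Igfbp2 and Glycam1 held in 3 and 2 of 7 fits.

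Some genes stood out in a single library over all cells. Rod-depleted OIR replicate 2 at P14 had Lcn2 at 8.98 per 10000 (highest other library 0.453) and Spp1 at 2.37 (0.346). Replicate 1 of the same group had Il6 at 0.303 (0.0711) and Bri3 at 0.854 (0.209). Rod-depleted OIR at P17 had the tip-cell gene Esm1 at 0.361 (0.0421) and the macrophage genes Mrc1 at 0.418 (0.0974) and Ms4a7 at 0.430 (0.0732). Whole-retina NORM at P17 had the pigment-cell genes Dct at 2.25 (0.498) and Mlana at 0.420 (0.0913).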
